A study of Homo sapiens with 4 samples.

How the data were processed

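The data were RNA-seq libraries of HEK293T cells, 2 with empty vector and 2 with a tRNA-LeuTAA plasmid. Per the labels, 1 ug of total RNA was poly(A)-selected and made into libraries with a directional kit. Libraries of other tRNA plasmids were not analysed here. Groups and replicate numbers were taken from the labels.

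The authors deposited 1 abundance table per library, with estimated counts, TPM (length-scaled transcript abundance), length and effective length for 58327 transcripts. The submitters' processing notes name kallisto, DESeq2 and hg38, and versions are not given in the sources used here. The deposited estimated counts are fractional where reads were shared between transcripts: 54.7 to 56.0% of transcript values were not whole. The deposited TPM values were not tested, because the effective lengths differ in kind between libraries. In transcripts without counts, length minus effective length implied a mean fragment length of 184 bases for empty vector replicate 1, 207 and 206 bases for the tRNA-LeuTAA libraries, and 0 for empty vector replicate 2. Transcripts under 200 bases accordingly held 7.65, 1.10, 6.20 and 11.7% of TPM in empty vector replicates 1 and 2 and tRNA-LeuTAA replicates 1 and 2.

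Transcripts were named through a RefSeq gene table of GRCh38.p14 (57213) or GENCODE 29 (671), and 351 without a name were left out. They held 0.0752 to 0.100% of the counts. The expected counts were summed into 27009 genes and rounded to whole numbers. The tables also list 92 sequences with the accessions of a synthetic spike-in set that the labels do not mention. They held 0.266 and 0.116% of counts in empty vector and 0.484 and 0.215% in tRNA-LeuTAA, and were kept out of library sizes and tests. The 28S ribosomal RNA share was 0.372 and 0.153% in empty vector and 0.339 and 0.158% in tRNA-LeuTAA.

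Genes passing filterByExpr (16324) were tested with edgeR 4.0.16 (TMM, glmQLFit and glmQLFTest, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common biological coefficient of variation was 0.156. CPM values are gene counts scaled by the TMM library sizes. DESeq2 1.42.0 and limma 3.58.1 (voom, camera, fry) were alternatives or set tests; camera used a preset correlation of 0.01, adjusted over 23 lists. Python 3.11.15, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 served for tables, permutation tests and plots. No pair of libraries agreed within sampling noise (chi-square per degree of freedom 15.4 to 52.2).

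The gene lists, the tests, the main alternative settings and the rule for named genes were fixed before the data were examined. The rule named up to 12 called genes per direction with a mean of at least 5 CPM in the higher group and groups that did not overlap, up to 4 called members per list, the member with the smallest p in a list without calls, and the 5 genes with the smallest p in a direction with fewer than 5 calls. Of the genes this rule named, 2 are not reported here. Other list members, and the list members not tested for low counts, were named after their values were seen. Alternatives covered normalization, filters, tools, a replicate block, each library left out, transcripts, effective-length offsets and protein-coding genes. Those restricted to genes with whole counts (within 0.001), with a robust fit, or with each library's GC trend removed were chosen after seeing the data.

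For the seed-site test, 3' UTRs came from GENCODE 29 through its RefSeq matches (18872 genes), using the coding transcript with the most counts per base. The plan had named the most abundant transcript and a look-up of the fragment in a genome; TPM was not comparable and a genome sequence was not used here. Matched lengths were within 10% for 74.4% of these genes.

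The gene test was tested on simulated counts for 16100 genes with 200 changed. It called 13.4% of genes changed 1.5-fold, 68.7% of those changed 2-fold and 98.5% of those changed 4-fold, with 0 false calls among 120. In the main fit of the real data, 8 of the 35 interferon list members tested were called. That list's median log2 fold change was 2.13, so the simulated shares need not hold for these libraries. Intervals cover counting error only. Floors (3 counts) stand for counting error in the empty-vector group only, with the tRNA-LeuTAA counts taken as they are.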

Results

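RNA was sequenced from HEK293T cells, an established human embryonic kidney line, that had been transfected 4 times at intervals of 2 days. The cells received either a plasmid expressing the leucine tRNA with anticodon TAA (tRNA-LeuTAA), the source of the fragment tRF-3009, or the empty vector pcDNA3. Each group had 2 libraries, made from poly(A)-selected RNA with a strand-marking kit. The estimated counts per library summed to 27863024 and 28526573 for empty vector and to 32202416 and 25810913 for tRNA-LeuTAA. Poly(A) selection leaves the tRNA and its fragments out of these libraries, so the level of the expressed tRNA was not measured. The labels number the replicates without saying that they were separate cultures, so the p-values measure the spread between these libraries, which may be technical.

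The comparison of tRNA-LeuTAA with empty vector asked which genes change when this tRNA and its fragments are in excess. Interferon-stimulated genes were higher in tRNA-LeuTAA cells. IFIT1, an antiviral protein that binds foreign RNA, rose 15.4-fold, from 5.97 ± 1.68 to 91.5 ± 8.45 CPM (depth-scaled counts; SD, n = 2). IFI6, a mitochondrial protein induced by interferon, rose 7.89-fold, from 6.64 ± 2.01 to 52.3 ± 1.30 CPM (SD, n = 2). Of 16324 genes tested, 8 were higher and 0 were lower at an adjusted p of 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). At an unadjusted p of 0.05, 290 genes were higher and 347 lower. These 637 are fewer than a share of 0.05 of the genes tested, which chance alone would give. Such a shortfall does not show that the other genes were unchanged, and some settings given below called more. DESeq2 called 38 genes higher and 10 lower, and limma-voom called 11 higher and 0 lower.

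All 8 called genes belong to the interferon response list. IFIT2 had a log2 fold change of 4.38 ± 0.26 (SE), with 0.694 and 0.606 CPM in the empty-vector libraries and 12.2 and 14.9 CPM in the tRNA-LeuTAA libraries. IFI44L had a log2 fold change of 4.15 ± 0.22. ISG15, a ubiquitin-like modifier, had one of 3.77 ± 0.32, and IFI6 one of 2.98 ± 0.23. IRF9, a transcription factor of the interferon pathway, had one of 2.66 ± 0.21. IFI44 had 1 count in each empty-vector library against 69 and 67 counts in the tRNA-LeuTAA libraries, a ratio of 66.2 with a 95% counting interval from 18 to 552 that covers counting error only. The adjusted p-values of the 8 genes ran from 0.0151 for IFI44L, IFIT1 and IFIT2 to 0.0456 for ISG15 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). Called genes numbered 175 higher and 136 lower without empty vector replicate 1, 43 and 15 without empty vector replicate 2, 18 and 1 without tRNA-LeuTAA replicate 1, and 29 and 14 without tRNA-LeuTAA replicate 2, and the same 8 genes were called in each. Of the 8, 6 were called with a stricter filter on counts and 3 with effective lengths as offset.

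On genome build hg38, IFI44L lies on chromosome 1 from 78620448 to 78646145, next to IFI44 from 78649789 to 78664078. IFIT2 lies on chromosome 10 from 89302046 to 89309271 and IFIT1 from 89392623 to 89406487. ISG15 lies on chromosome 1 from 1013497 to 1014540 and IFI6 on the same chromosome from 27666064 to 27672192. IRF9 lies on chromosome 14 from 24161265 to 24166565. These genes are annotated as protein-coding.

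**Figure D1:**
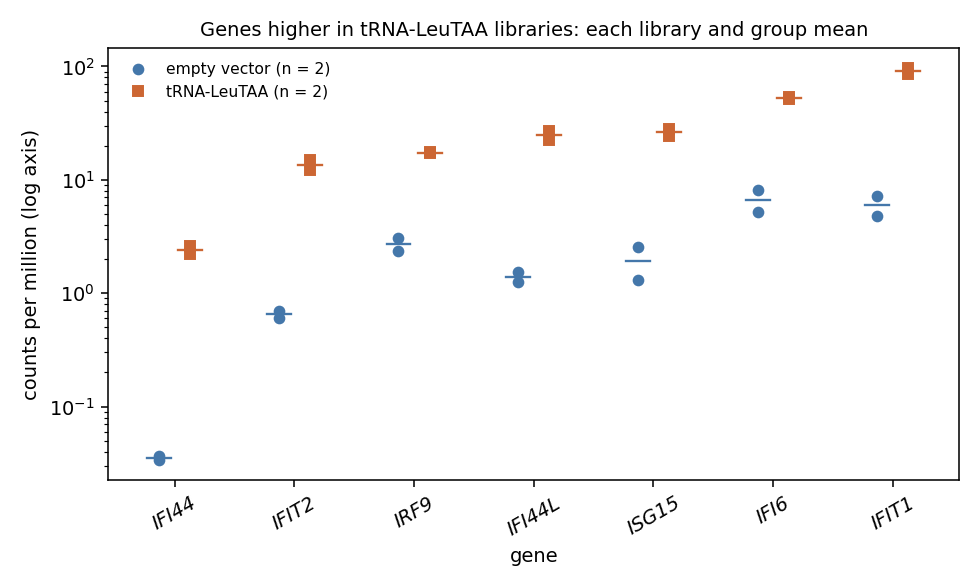
CPM on a log axis for 7 of the 8 genes called higher, with circles for the empty-vector libraries, squares for the tRNA-LeuTAA libraries (2 each) and short lines for group means. Both tRNA-LeuTAA libraries lie above both empty-vector libraries for each gene shown, as for IFIT1 with 85.6 and 97.5 against 7.15 and 4.78.

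Of the 35 interferon list members tested, 8 rose at an adjusted p of 0.05 over all genes, and 28 rose when adjusted over the list alone. Both tRNA-LeuTAA libraries exceeded both empty-vector libraries for 34 of the 35, where chance gives 16.7% for each member in this direction. The members are not fully independent (estimated correlation 0.045). The list's median log2 fold change was 2.13. The 2 members at 0 counts in empty vector also lie above it with that group set at a floor of 3 counts. Setting them there gives 2.13 by construction. Against other genes the list was higher (camera, adjusted p = 3.0e-244), and this held at adjusted p = 0.037 with an estimated correlation. The cytosolic RNA sensors RIGI and IFIH1 had log2 fold changes of 2.13 and 1.48 and by edgeR passed the adjustment over the list alone, not that over all genes; DESeq2 called both, and 25 members in all, over all genes. OAS1 had 0 counts in both empty-vector libraries and 39 and 37 counts in tRNA-LeuTAA. That is 24.7-fold higher with the empty-vector group set at a floor of 3 counts. CXCL10, a chemokine, had 0 counts against 26 and 22, 15.6-fold higher on the same floor. Members near their empty-vector level were USP18 (log2 fold change 0.26), STAT2 (0.26) and ISG20 (-0.38), none past either adjustment.

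Genes of the integrated stress response, which ATF4 drives when amino acids are short, were lower as a group. The list's median log2 fold change was -0.61 over 31 tested members, 30 of them negative (camera, adjusted p = 5.7e-23). The group's call was lost at adjusted p = 0.83 with an estimated correlation. Both tRNA-LeuTAA libraries were below both empty-vector libraries for 24 members, where chance gives 16.7% for each member in this direction. The members varied together (estimated correlation 0.424), so the 24 are not independent and their number is no test of the list. By edgeR 0 members passed the adjustment over all genes, 18 had an unadjusted p under 0.05, and 1, PCK2, passed when adjusted over the list alone; DESeq2 called 2, PCK2 and TRIB3. PCK2, the mitochondrial enzyme that makes phosphoenolpyruvate, had 88.6 and 96.7 CPM in empty vector and 47.6 and 48.8 CPM in tRNA-LeuTAA, a log2 fold change of -0.94 ± 0.12. Its adjusted p over all genes was 0.183 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment), and it was called without the filter and with either empty-vector library left out, but not with either tRNA-LeuTAA library left out. TRIB3 had a log2 fold change of -1.06, DDIT3 of -0.90, ASNS, which makes asparagine, of -0.45, and ATF4 itself of -0.05. The list's median was -0.37 without empty vector replicate 2 and -0.41 without tRNA-LeuTAA replicate 1.

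Heat shock genes had a median log2 fold change of 0.34 over 17 members (camera, adjusted p = 4.8e-06), with adjusted p = 0.93 with an estimated correlation. The chaperone HSPA8 had 902 and 239 CPM in empty vector and 1780 and 1047 in tRNA-LeuTAA, so it differed within each group as well, and the list's adjusted p was 0.054 without empty vector replicate 2. The smallest p in the list was that of DNAJA1, with a log2 fold change of 0.87 that did not pass. Cholesterol synthesis genes had a median of 0.16 over 24 members (camera, adjusted p = 0.0051; adjusted p = 0.95 with an estimated correlation). Genes of G2 and mitosis had a median of 0.09 over 28 members (camera, adjusted p = 0.020; adjusted p = 0.95 with an estimated correlation), led by DLGAP5 at 0.25. Without empty vector replicate 2 the cholesterol list had an adjusted p of 0.68 and the mitosis list 0.60 by camera, and the mitosis list had one of 0.41 without tRNA-LeuTAA replicate 1. In these 3 lists 0 members passed by edgeR in the main fit, over all genes or adjusted over the list alone. An unadjusted p under 0.05 was reached by 4 members, and DESeq2 called 1, DNAJA1.

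The other 18 lists did not pass camera's test in the main fit. In that fit 0 of their members passed by edgeR, over all genes or adjusted over the list alone. An unadjusted p under 0.05 was reached by 16 members, and DESeq2 called 0. Some of the members named here, DICER1 among them, were called by edgeR with the replicate block, as given below. Small RNA silencing genes had a median of -0.0026 over 30 members, with DICER1, the enzyme that cuts microRNA precursors, at 0.49 ± 0.11 (SE). DICER1 had 119 and 114 CPM in empty vector and 161 and 165 CPM in tRNA-LeuTAA, with an adjusted p of 0.969 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). Medians were 0.08 for tRNA processing and transcription, led by POP1 at 0.46, and -0.02 for aminoacyl-tRNA synthetases, led by CARS1 at -0.45. They were 0.01 for leucine sensing, mTORC1 and lysosome (NPRL3 at -0.36), 0.08 for the unfolded protein response (ERN1 at -0.44) and -0.04 for ribosomal proteins (RPS28 at -0.22). Medians were 0.01 for glycolysis and hypoxia (VEGFA at -0.60), 0.05 for oxidative phosphorylation (SDHD at 0.25), 0.04 for G1/S and replication (RRM2 at 0.34) and 0.01 for p53 targets (BBC3 at -0.57). They were -0.10 for immediate early genes (KLF6 at -0.25), 0.02 for NF-kB genes (TNFAIP3 at 0.40), -0.07 for KRAB zinc fingers (ZNF34 at -0.39) and 0.01 for histones (H2AC6 at -0.47). Markers of other cell types had medians of 0.03 for fibroblasts (TAGLN at 0.41), -0.13 for epithelium (MUC1 at 0.73), -0.05 for blood (LCP1 at -0.56) and 0.04 for neurons (INA at 0.28).

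**Figure D2:**
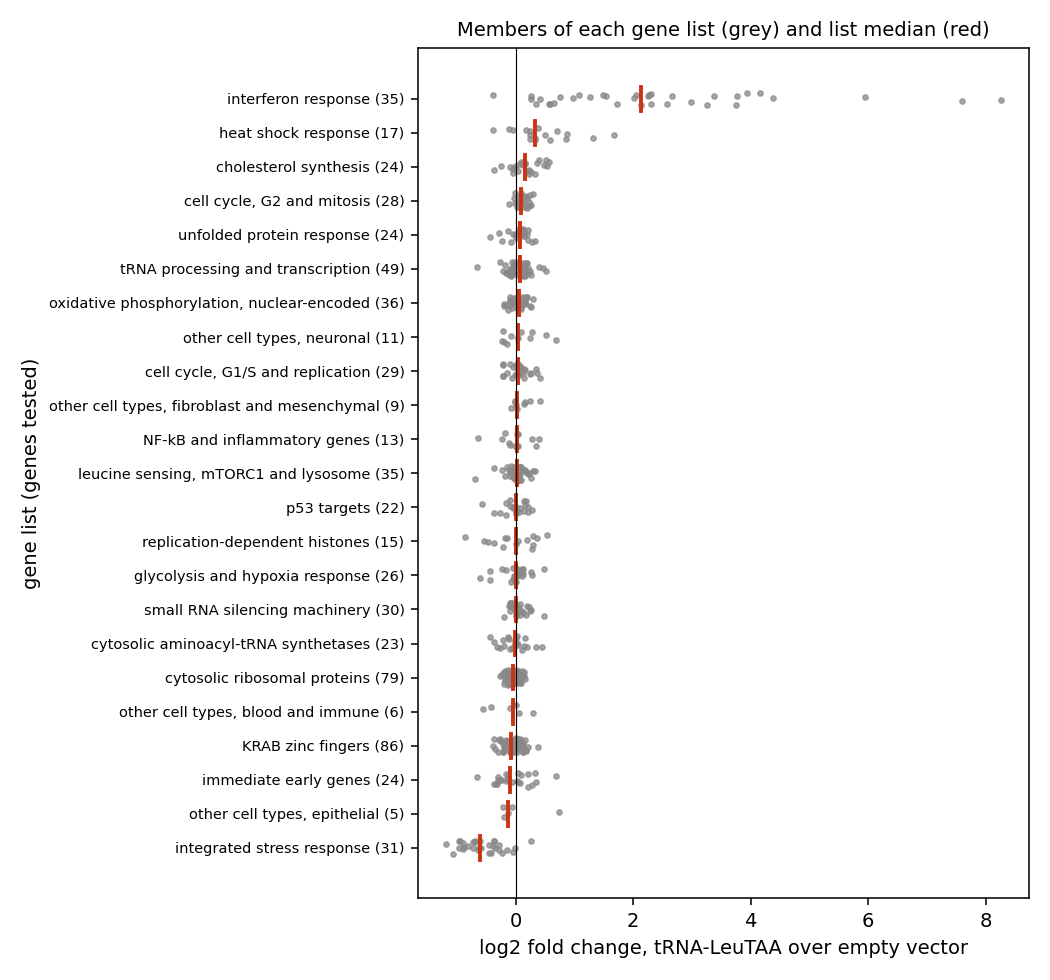
Log2 fold changes of the tested members of 23 gene lists (grey points, jittered vertically), with each list's median as a red line and the number tested in brackets. The interferon list has a median of 2.13 and the integrated stress response list one of -0.61.

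Among genes with negative fold changes, the smallest p-values by edgeR after PCK2 belonged to 4 genes that also did not pass; DESeq2 called all 4 lower, as did edgeR with either empty-vector library left out, but not without tRNA-LeuTAA replicate 1. RN7SL2, an RNA of the signal recognition particle, had 69.5 and 54.1 CPM in empty vector and 29.6 and 28.3 CPM in tRNA-LeuTAA, a log2 fold change of -1.09. It is nearly identical to RN7SL1 and lacks a poly(A) tail, so its level is uncertain. G0S2, an inhibitor of lipolysis, had a log2 fold change of -1.35. The read-through loci MICOS10-NBL1 (-1.99) and SLMO2-ATP5E (-1.45) share exons with their neighbours, and their estimates are uncertain for that reason.

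The series asks whether tRNA fragments repress genes, and small RNAs usually pair with messages through bases 2 to 8. Genes with a match to these bases of tRF-3009 were close to other genes in tRNA-LeuTAA cells. The 18-base fragment was taken as ACCCCACTCCTGGTACCA, from general knowledge of the tRNA, and was not looked up in a genome. Its site AGTGGGG occurred in the 3' UTR of 1822 tested genes and was absent from that of 12015. The median log2 fold change was -0.03 with the site and -0.01 without, a difference of -0.0189 (camera p = 0.326, two-sided, n = 1822 genes with the site). By library, the mean difference was -0.00879 ± 0.00312 (SD, n = 2) in tRNA-LeuTAA and 0.0113 ± 0.0217 (SD, n = 2) in empty vector. Those groups gave an exact two-sided permutation p of 0.333, the smallest this design allows. Of the 42 arrangements of the site's bases, 21 had a difference as low or lower, its own included. None of the 8 interferon genes called higher carried the site. The sign turned without empty vector replicate 1 (0.00352) and with each library's GC trend removed (0.00428). In simulated data a shift of -0.2 in the genes with the site was recovered as -0.20. A smaller shift, or one in only some of these genes, was not simulated, so such repression is left open.

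**Figure D3:**
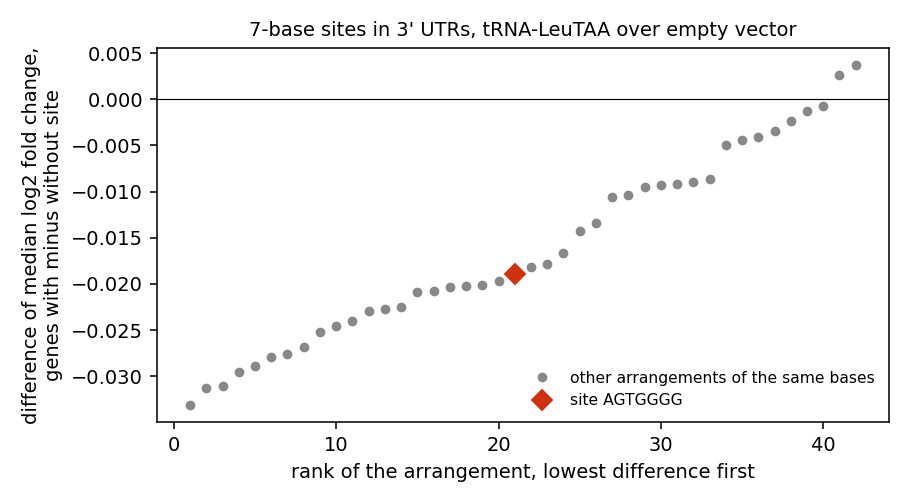
Difference in median log2 fold change between genes with and without a 7-base site in the 3' UTR, for the 42 arrangements of the same bases ranked from lowest. The red diamond is the site of tRF-3009, at rank 21 with a difference of -0.0189.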

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

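The spike-in tests were chosen after their result was seen.

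The synthetic spike-in sequences, data outside the gene comparison, differed between the groups. Of 38 with at least 10 counts in each library, 9 had a share of spike-in counts over 2-fold higher in tRNA-LeuTAA, with log2 ratios from 1.48 to 1.94, while the other 29 lay between -1.66 and 0.08. Length bias is argued against: of the 9, 1 had another of the 9 as its nearest neighbour in length, with ties counted as such. Chance gives 1.95 where each sequence has a single nearest neighbour, without ties. An earlier permutation test of the lengths gave p = 0.397 (n = 38 sequences). Sequences picked in the replicate 1 libraries stood apart from the others in the replicate 2 libraries by a gap of 1.29, wider than the largest gap among the others, which is consistent with a different spike-in mixture in each group. No biological explanation was tested, since the sequences are not cellular.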

How the results depend on the processing

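The alternatives limited to whole counts, with a robust fit or with GC trends removed were chosen after seeing the data. With 2 libraries per group the test called few 1.5-fold changes in simulated data, and lists near 0 have no settled sign. Of 88 values for the 8 called genes under 11 alternatives each, 88 kept their direction and 82 stayed past the threshold, with a largest adjusted p of 0.0798 (edgeR quasi-likelihood test). These do not include the stricter filter, which tested all 8 and called 6. The interferon list stayed past the threshold in each alternative, with medians from 1.99 to 2.19. The cause was not tested for the changes below, except that whole counts and left-out libraries mean fewer genes or samples; a lone library is assumed to vary like the other group.

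Genes called numbered 25 (24 higher, 1 lower) without the filter, 48 (38 and 10) by DESeq2, 3 (3 higher) with effective lengths as offset and 5 (5 higher) among whole counts. Transcripts tested separately gave 0 by edgeR, with 1624 at an unadjusted p of 0.05. With a library left out, 19 to 311 were called, 18 to 175 higher and 1 to 136 lower. With the replicate block, 630 genes were called, 338 higher and 292 lower. Of 25 named genes without a call in the main fit, the replicate block called 13, of which 7 (DICER1, CARS1, POP1, VEGFA, RRM2, NPRL3 and BBC3) were called in no other alternative; DESeq2 called the other 6 (PCK2, DNAJA1, RN7SL2, G0S2, MICOS10-NBL1 and SLMO2-ATP5E), as did edgeR without empty vector replicate 1, and 12 were called in none. The labels do not say that a replicate number marks a batch (2 pairs), but some values went with it: same-number deviations had a correlation of 0.275, 28S ribosomal RNA held 0.372 and 0.339% of counts in the replicate 1 libraries against 0.153 and 0.158%, and empty vector replicate 1 was nearer to tRNA-LeuTAA replicate 1 than to empty vector replicate 2 (chi-square per degree of freedom 15.4 and 48.2). Likewise tRNA-LeuTAA replicate 1 was nearer to empty vector replicate 1 (15.4) than to tRNA-LeuTAA replicate 2 (19.7). Empty vector replicate 2 was nearer to tRNA-LeuTAA replicate 2 (24.1) than to empty vector replicate 1 (48.2). Only tRNA-LeuTAA replicate 2 was nearer to the other library of its group (19.7) than to its same-number library (24.1). The replicate block left 5 gene lists past the threshold and the seed-site difference at -0.0195. Lists past the threshold numbered 1 with an estimated correlation, 1 by fry, 2 among whole counts and 5 to 10 with a library left out. Among whole counts the heat shock list had too few members to be tested. The 4 lists lost with an estimated correlation and by fry kept their medians by construction (-0.61 for integrated stress response, 0.34 for heat shock, 0.16 for cholesterol, 0.093 for mitosis).

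With a library left out, median log2 fold changes spanned 0 for tRNA synthetases (-0.082 to 0.011), silencing genes (-0.022 to 0.050), ribosomal proteins (-0.21 to 0.16), glycolysis (-0.17 to 0.32), oxidative phosphorylation (-0.078 to 0.22), p53 targets (-0.044 to 0.11), NF-kB genes (-0.038 to 0.15), zinc fingers (-0.25 to 0.22), histones (-0.17 to 0.20), fibroblast markers (-0.31 to 0.50) and neuronal markers (-0.079 to 0.22). Ribosomal proteins, glycolysis and zinc fingers passed the threshold in both directions among these fits. MUC1 (-0.038 to 1.27), RPS28 (-0.45 to 0.060) and seed-site genes (-0.0428 to 0.00352) also spanned 0. Medians ran from 0.089 to 0.23 for cholesterol, 0.043 to 0.22 for mitosis and 0.19 to 0.52 for heat shock. For integrated stress response they ran from -0.81 to -0.37. These fits kept camera's preset correlation, so they do not bear on the calls lost with an estimated correlation.

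With library totals, signs turned for glycolysis (-0.033), G1/S (-0.0091), p53 targets (-0.036), NF-kB genes (-0.024), leucine sensing (-0.030), histones (-0.041), fibroblast (-0.0094) and neuronal markers (-0.00090). With effective lengths they turned for ribosomal proteins (0.17), RPS28 (0.18), glycolysis (-0.019), p53 targets (-0.023) and NF-kB genes (-0.055). Ribosomal proteins, oxidative phosphorylation (0.18) and histones (0.26) then passed the threshold and cholesterol (0.17) did not. Without the filter signs turned for blood (0.0086) and neuronal markers (-0.021), and with DESeq2 size factors for silencing genes (0.00018). Among whole counts they turned for tRNA synthetases (0.019), ribosomal proteins (0.0037) and histones (-0.12), and cholesterol (0.011) and mitosis (0.13) no longer passed. With GC trends removed they turned for silencing genes (0.012), histones (-0.013) and seed-site genes (0.00428), and mitosis (0.061) no longer passed.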

Other observations

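The tests of reads shared between genes, GC content, the left-out library, RNA content and RNA polymerase III transcripts were chosen after the patterns were seen; for GC content and RNA polymerase III transcripts the bounds were written before the values tested.

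IFNB1, the gene of interferon beta, had 0 counts in both empty-vector libraries and 8 and 21 counts in tRNA-LeuTAA. That is 9.41-fold higher with the empty-vector group set at a floor of 3 counts. IFNL1 had 0 counts against 5 and 1, and MX2 had 0 and 2 counts against 1 and 7. These genes did not pass the main filter. Without it 0 of the 3 were called by edgeR or DESeq2, with adjusted p-values for IFNB1 of 0.58 (edgeR) and 0.31 (DESeq2). DESeq2 called 13 genes higher outside the fixed list: HELZ2 (log2 fold change 1.44), EPSTI1 (2.07), LUZP6 (1.17), SAMD9 (1.71), PARP9 (1.37), LGALS3BP (0.99), ZC3HAV1 (0.84), PLSCR1 (0.89), DTX3L (1.32), MAT2A (0.92), DNAJA1 (0.87), and GOLGA6L6 and CNTF, which had 0 counts in at least 1 empty-vector library. It called 10 lower: MICOS10-NBL1 (-1.99), SLMO2-ATP5E (-1.45), RN7SL2 (-1.09), PCK2 (-0.94), G0S2 (-1.35), RN7SL1 (-0.92), TRIB3 (-1.06), the amino acid transporter SLC43A1 (-0.85), and SNORD141A and SNORD141B, which had counts in empty vector replicate 2 only.

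The higher interferon list was weighed against 3 technical explanations. Members with whole counts in each library had a median log2 fold change of 2.04, which argues against reads shared between related genes. The median was 2.18 with each library's GC trend removed, and 2.08 without empty vector replicate 2, whose fragment length setting differs. An interferon response to the tRNA plasmid or its RNA may account for the pattern, as a hypothesis that was not itself tested. A difference between the plasmid preparations, which the labels do not describe, goes with the groups and was not tested.

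The lower integrated stress response list had a median log2 fold change of -0.53 with each library's GC trend removed and -0.37 without empty vector replicate 2. The standard error of the group difference between libraries was 0.276, so neither value settles whether GC content or that library could account for part of it. A lower demand on this pathway in tRNA-LeuTAA cells stays open and was not tested.

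Neither of the further hypotheses was settled. A lower level of RNA polymerase III transcripts as a class would lower others beside RN7SL1 and RN7SL2. Yet the 5 others tested had a median log2 fold change of -0.18. The group difference of their mean log2 CPM had a standard error of 0.550 between libraries. All of them but BCYRN1 were at 4.56 CPM or lower in each library. The 4 tested RNA polymerase II transcripts without a poly(A) tail, all at low counts, had a median of -0.43. Less messenger RNA per unit of total RNA would raise the other spike-in sequences relative to gene counts. Their log2 ratio was 0.22, with 2333 and 1000 CPM in empty vector and 2649 and 1201 CPM in tRNA-LeuTAA (exact two-sided permutation p = 0.667). The test took no account of replicate numbers, and at each number the tRNA-LeuTAA value was the higher. The unequal ratios among the spike-in sequences leave this measure open as well.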
